A study of Mus musculus with 10 samples.

How the data were processed

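RNA was measured in primary liver sinusoidal endothelial cells of mice, the specialised endothelium that lines the sinusoids, the capillaries of the liver. The labels put 5 samples in a group called Gata4-LSEC-KO here and 5 in a control group of sibling mice. In the first group a Cre recombinase transgene under control sequences of Clec4g, a gene expressed in liver sinusoidal endothelium, was combined with a floxed Gata4 gene, which encodes a zinc finger transcription factor. Per the labels' protocols, livers were perfused with collagenase, the tissue of 3 mice was pooled for each sample, nonparenchymal cells were separated on a density gradient, and endothelial cells were taken with magnetic beads against CD146, the product of Mcam. The labels call the samples of a group biological replicates. They give no batch, array date, sex or age.

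Total RNA was hybridised to 1-colour Affymetrix arrays with a biotin label, per the labels. The deposited values were made with RMA (background correction, quantile normalization and summarization of probes into probe sets), per the submitters' processing notes, which give no version. The authors' deposited values are on a log2 scale, judged from their range and median (each array's median was 3.71). The sorted values were identical in 9 of the 10 arrays and differed by at most 0.00186 in the tenth, so the arrays had already been brought to one distribution, and no further normalization was applied. The array design, the probe locations and any genome build are not given in the sources used here. Detection calls and scanner files were not used here, so no gene can be called absent and no other background correction was tried. A fold against a group mean near or under the array median, as for Aplnr, Apln, Mcemp1, Jag2 and Cd209a, is a ratio of array values and not of RNA amounts. The number of arrays, 5 per group, limits the precision.

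Of 25428 probe sets, 24705 had 1 gene symbol in the platform annotation, 0 had several and 723 were unnamed here and were left out. Symbols were compared by Entrez gene number with a RefSeq gene table of the mouse assembly GRCm38.p6. It held 24673 of them, and 0 symbols needed an update. That table also gave the order of genes along chromosomes. 1 symbol had more than 1 probe set and was represented by the brighter, which left 24704 genes. No columns were left unused, no pair of arrays held identical values, and no array was left out of the main comparison.

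Knockout and control were compared with limma (version 3.58.1, R version 4.3.3), using lmFit and eBayes without an intensity trend, on all 10 arrays, without covariates and without a filter on dim genes. All tests ran in both directions. P-values were adjusted by the Benjamini-Hochberg method over the 24704 genes, with a threshold of 0.05. Log2 fold changes are knockout minus control and are given ± their standard error (SE). Group means are given ± SD with n = 5. P-values measure the spread between pools of 3 mice.

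Before the data were examined, 32 gene lists were fixed: 19 endothelial programmes and signalling groups, and 13 lists of markers of other cells, dissociation stress and sex-linked genes. They name 413 different genes, and 22 list entries were not measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, adjusted over the 32 lists. Beside it stand camera with the correlation estimated per list, and fry, which asks whether a list's genes moved, on balance, one way (directional) or changed in either direction (mixed). The lists for sinusoidal and capillary markers, profibrotic ligands, matrix genes and MYC targets match themes already known for this mouse model, so they are not independent evidence of a direction.

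The genes named in the text follow a rule that was also fixed before the data were examined. Gata4 came first. Next came the 10 genes with the largest log2 fold change in each direction among those past the threshold whose group values did not overlap, without predicted genes, small RNAs and immunoglobulin or T cell receptor segments. From each list came up to 4 members past the threshold with the largest change, or, where none passed, up to 2 with the smallest p. A further 15 genes were always reported. Genes named outside this rule are said to have been chosen after their values were seen.

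The procedure was tested on simulated data with the means and spreads of the 24704 genes, 10 times, with 200 changed genes each time. For this comparison of 5 with 5 arrays, it recovered 11.9% of genes changed 1.41-fold, 79.9% of those changed 2-fold and 98.0% of those changed 4-fold, and 4.97% of its calls were false. A shifted list was found in 10 of 10 simulations, and 0 of 310 unshifted lists were called. The simulated genes varied independently, so these rates, the false share included, need not hold for genes that vary together. In the real lists the estimated correlation reached 0.865.

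The alternatives fixed before the data were examined were quantile normalization, median centring, 2 filters on dim genes, the mean of all probe sets of a gene, an intensity trend with robust variances, array weights, the replicate number as a block, 3 marker list means as covariates (hepatocyte, Kupffer cell, stellate cell) and the omission of each array in turn. Chosen after seeing the data were the neutrophil and cholangiocyte list means as covariates and the omission of the genes next to Clec4g.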

Results

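Liver sinusoidal endothelial cells from mice with a Gata4 deletion driven by Clec4g-iCre and from sibling controls were profiled on 10 arrays, 5 per group, each array holding the RNA of a pool of 3 mice. The single comparison implied by this design asks what the deletion of Gata4 in these cells changes in their transcriptome. "Knockout" stands for the label of the arrays throughout. Markers of sinusoidal endothelium were lower in the knockout (the protease gene Ctsl 1.66-fold), and markers of continuous capillaries were higher (the apelin receptor gene Aplnr 11.7-fold and Cd34 3.01-fold). Basement membrane genes such as Nid2 (3.67-fold), the growth factor gene Pdgfb (4.35-fold) and the transcription factor gene Myc (3.25-fold) were higher, while the ligand genes Wnt2 (2.11-fold) and Bmp2 (2.09-fold) were lower. Markers of neutrophils such as S100a8 (log2 fold change 3.16) were higher as well. Each of these is given with its error in the account of its group.

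The targeted gene itself did not separate the groups. The Gata4 probe set read 8.59 ± 0.24 (SD, n = 5) in the knockout and 8.71 ± 0.15 (SD, n = 5) in the control arrays, a log2 fold change of -0.12 ± 0.13 (SE) with an adjusted p of 0.742 by limma. Where the probes of this set lie relative to the deleted part of the gene is not given in the sources used here, so the value does not check the labels. The related factors Gata6 (log2 fold change 0.54 ± 0.24, adjusted p = 0.353) and Gata2 (0.33 ± 0.14, adjusted p = 0.311) also did not pass the threshold.

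The knockout arrays nevertheless differed widely from the controls. Of 24704 genes, 529 passed the threshold, 320 higher and 209 lower in the knockout. The changes upward were larger: 198 genes were at least 2-fold higher and 40 at least 2-fold lower. The group values did not overlap for 503 of the 529 genes. Over all genes, 4.93% had groups that did not overlap, where chance gives 0.794%. The count depended on which arrays were used. It fell to 349, 295 and 317 without knockout replicates 1, 2 and 4, and to 321, 321 and 287 without control replicates 3, 4 and 5, and was 550 without knockout replicate 5. The count of genes higher fell to 189 and 199 without knockout replicates 2 and 4, and to 206, 207 and 182 without control replicates 3, 4 and 5. That of genes lower fell to 126, 106 and 118 without knockout replicates 1, 2 and 4, and to 124, 115, 114 and 105 without control replicates 2, 3, 4 and 5. Control replicate 1 stood apart from the other arrays, with correlations across genes of 0.920 to 0.944 against 0.969 to 0.988 among the other 9. Without it 737 genes passed, 343 of them lower. With all arrays, array weights gave 1070 genes, and the replicate number as a block gave 275 (200 higher and 75 lower).

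**Figure D1:**
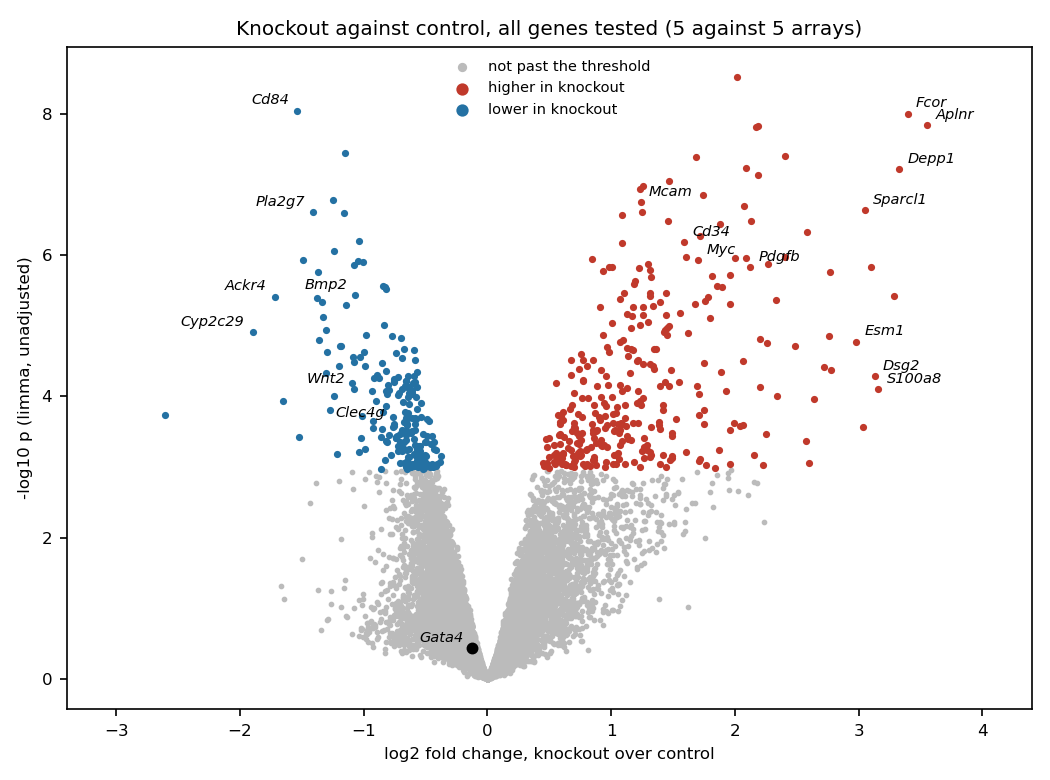
Volcano plot of the 24704 genes, with the log2 fold change of knockout over control on the x axis and -log10 of the unadjusted limma p on the y axis. Red points mark the 320 genes higher and blue points the 209 lower in the knockout, and the black point marks Gata4 at a log2 fold change of -0.12.

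The strongest increase was in Aplnr, the receptor of the peptide apelin, which was 11.7-fold higher (log2 fold change 3.55 ± 0.25, adjusted p = 6.37e-05) and read 7.13 ± 0.53 in the knockout against 3.57 ± 0.36 in the control (SD, n = 5). Depp1, a target of FOXO transcription factors, rose by 3.33 ± 0.27 on the log2 scale. Sparcl1, a matricellular protein, rose by 3.05 ± 0.28, and Esm1, the endothelial proteoglycan endocan, by 2.98 ± 0.42. Lcn2 (lipocalin 2, 3.29 ± 0.40), the desmosomal cadherin Dsg2 (3.13 ± 0.50), S100a8 (3.16 ± 0.53) and Tm4sf4 (3.04 ± 0.59) rose as well. Of these, S100a8 is in the neutrophil and monocyte list. Among the knockout arrays Dsg2 and Tm4sf4 were highest in replicates 1 and 2 and lowest in replicate 5, as was the cholangiocyte list mean. Whether their rise came from other cells was not tested. Fcor (3.40 ± 0.23) and Mcemp1 (3.10 ± 0.34) were also among the 10 largest increases, and both lie within 5 measured genes of Clec4g on the chromosome. The call of Tm4sf4 ended without knockout replicate 1, 2 or 4 or control replicate 4 or 5, where its adjusted p reached 0.0658.

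The decreases were smaller. Cyp2c29, a cytochrome P450 known from hepatocytes, was lowest among the genes whose groups did not overlap, at -1.90 ± 0.26 (adjusted p = 0.00297). The atypical chemokine receptors Ackr4 (-1.72 ± 0.21) and Ackr1 (-1.65 ± 0.29) fell, as did Cd84, a SLAM family receptor, at -1.54 ± 0.10 with an adjusted p of 6.37e-05. Olfm1 (-1.49 ± 0.16), the lipoprotein-associated phospholipase Pla2g7 (-1.41 ± 0.13), the podoplanin receptor Clec1b (-1.37 ± 0.17), Gramd1c (-1.37 ± 0.15) and adenosine deaminase, Ada (-1.36 ± 0.19), were also lower. Cyp2e1, a hepatocyte enzyme of the pericentral zone, was lower by limma at -1.52 ± 0.31 (adjusted p = 0.0268). Its call ended without knockout replicate 1 or 2 or control replicate 3, 4 or 5, where the adjusted p reached 0.0781.

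Markers of sinusoidal endothelium were lower in the knockout. Of 20 measured markers, 8 passed, all lower, and 12 did not pass. Adjusted over the list alone, 18 were lower. Their loss is a theme known for this model, so the list is not independent evidence of direction. The driver gene Clec4g was 1.69-fold lower (log2 fold change -0.76 ± 0.14), the lysosomal protease Ctsl 1.66-fold (-0.73 ± 0.11) and coagulation factor F8 1.57-fold (-0.65 ± 0.15). The complement regulator Cd55 (-0.68 ± 0.14) fell as well. Maf, a transcription factor, was also lower (-0.61 ± 0.10). Stab2, the hyaluronan scavenger receptor, read 10.67 ± 0.27 in the knockout and 11.21 ± 0.20 in the control (SD, n = 5), with a log2 fold change of -0.55 ± 0.15 and an adjusted p of 0.0974. Lyve1 was at 0.29 ± 0.27 with an adjusted p of 0.697. The list was called downward by camera (adjusted p = 4.21e-15, and 0.0494 with an estimated correlation). The count of 8 became 3, 2, 3 and 5 without knockout replicates 1, 2, 4 and 5, and 2, 2, 2 and 3 without control replicates 2, 3, 4 and 5. Of these calls, that of Clec4g ended without knockout replicate 1 or 2 or control replicate 2, 3 or 4 (adjusted p up to 0.0598). That of Cd55 ended without any array except knockout replicate 1 and control replicate 1 (up to 0.0901), and that of F8 without any except control replicate 1 (up to 0.116).

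Markers of continuous capillaries were higher. Of 20 measured markers, 10 passed and all 10 were higher, while the other 10 did not pass. With p adjusted over the list alone, 12 were higher and 2 lower. Whatever their p, 17 lay higher and 3 lower. The 3 were Cldn5, Gpihbp1 and Cav2, which did not pass and were chosen after their values were seen. Of these, Cldn5, a tight junction claudin, did not overlap between the groups. Its highest knockout value was 8.47 and its lowest control value 8.50. This list matches a theme known for the model and is not independent evidence of its direction. Besides Aplnr and Esm1, the apelin gene Apln rose 4.26-fold (log2 fold change 2.09 ± 0.22), the sialomucin Cd34 3.01-fold (1.59 ± 0.16) and lipoprotein lipase, Lpl, 3.41-fold (1.77 ± 0.40, adjusted p = 0.047). Endomucin, Emcn, rose (0.58 ± 0.12, adjusted p = 0.0253). The camera test gave an upward call for the list (adjusted p = 5e-12, and 0.0116 with an estimated correlation). The call of Emcn ended without knockout replicate 1, 2 or 4 or control replicate 2, 3, 4 or 5 (adjusted p up to 0.0758), and that of Lpl without any array except control replicates 1 and 4 (up to 0.117).

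Genes shared by endothelia of many organs did not shift in one direction as a list. Of 18 pan-endothelial genes, 1 passed and 17 did not, and 3 were higher adjusted over the list alone. The gene that passed was Mcam, which encodes the CD146 antigen used for the isolation and was 2.36-fold higher (log2 fold change 1.24 ± 0.11, adjusted p = 0.000242), reading 9.01 ± 0.10 against 7.77 ± 0.19 (SD, n = 5). Camera did not call the list with all arrays and no covariate (adjusted p = 0.231), but called it upward without knockout replicate 2 (0.0378) and with the hepatocyte (0.0367), neutrophil (0.0295) or cholangiocyte (7.26e-06) list mean as a covariate. Fry called it in either direction (adjusted p = 4.97e-08). Its median member was at -0.01, while its mean and its test pointed upward.

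**Figure D2:**
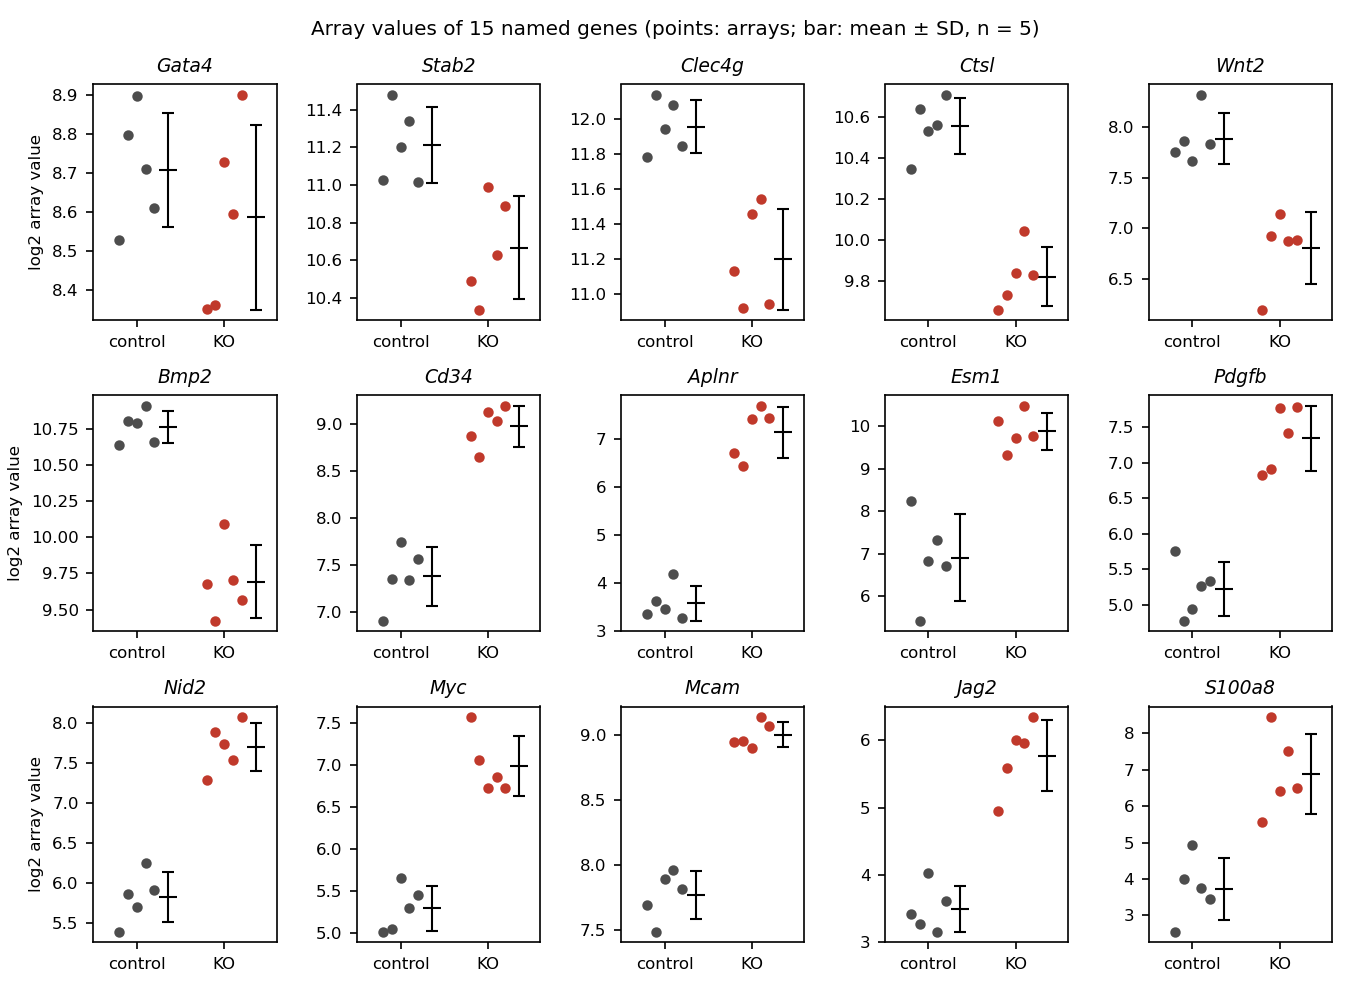
Array values (log2, y axis) of 15 named genes in the control and knockout (KO) groups, 1 point per array with replicates 1 to 5 from left to right, and bars for the mean ± SD (n = 5). The y axes differ between panels and do not start at 0; Gata4 overlaps between the groups, while Aplnr read 7.13 ± 0.53 in the knockout and 3.57 ± 0.36 in the control.

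Ligands through which the endothelium acts on hepatocytes were lower or did not pass. In the list of hepatotrophic angiocrine factors, 3 of 10 measured genes fell and 7 did not pass, and 4 fell adjusted over the list alone. Wnt2, a Wnt ligand of the pericentral endothelium, was 2.11-fold lower (log2 fold change -1.08 ± 0.18, adjusted p = 0.00981). Its call ended with the hepatocyte list mean as a covariate. Bmp2, the ligand that induces hepcidin in hepatocytes, was 2.09-fold lower (-1.07 ± 0.13, adjusted p = 0.00134), and Dkk3 was 2.52-fold lower (-1.33 ± 0.17). Wnt9b (-0.35 ± 0.16, adjusted p = 0.355) and Rspo3 (-0.14 ± 0.10, adjusted p = 0.609) did not pass. Camera called the list downward (adjusted p = 4.85e-05), but not with an estimated correlation (adjusted p = 0.0613).

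Zonal endothelial genes moved in both directions. Among 10 pericentral endothelial genes Wnt2 and Dkk3, both also in the angiocrine list, fell. Fabp4, a fatty acid binding protein, rose (1.22 ± 0.18), and 7 did not pass. Adjusted over the list alone, 1 was higher and 3 were lower. Camera called the list downward (adjusted p = 0.0242), but not with an estimated correlation (adjusted p = 0.300), and the call also ended without control replicate 4 (adjusted p = 0.0755). Among 10 periportal endothelial genes 1 passed, the chaperone Clu (1.27 ± 0.27, adjusted p = 0.0327), with 3 higher and 2 lower adjusted over the list alone. Camera did not call the list (adjusted p = 0.629), its median being -0.01 and its mean above 0, while fry called it in either direction (adjusted p = 3e-06). The call of Clu ended without knockout replicate 1, 2 or 4 or control replicate 3, 4 or 5 (adjusted p up to 0.0909).

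Among profibrotic ligands, Pdgfb, the platelet-derived growth factor chain that acts on pericytes and stellate cells, was 4.35-fold higher (log2 fold change 2.12 ± 0.23, adjusted p = 0.000744). It was the 1 member of 12 that passed, and 5 were higher adjusted over the list alone. The count was 2 without knockout replicate 1 or control replicate 1 or 5, and 4 without knockout replicate 5. An upward call came from camera (adjusted p = 1.98e-07, and 0.0079 with an estimated correlation). Genes of basement membrane and matrix rose as well. Of 19 measured, 8 rose, 1 fell and 10 did not pass, and 10 were higher and 2 lower adjusted over the list alone. Nid2 (nidogen 2) rose 3.67-fold (1.88 ± 0.18), fibronectin, Fn1, 2.77-fold (1.47 ± 0.24), Col15a1 2.52-fold (1.33 ± 0.17), the laminin chain Lamb1 2.38-fold (1.25 ± 0.22) and the type IV collagen chain Col4a1 2.10-fold (1.07 ± 0.15). The member that fell was Col13a1, a transmembrane collagen (-1.19 ± 0.17), which was chosen after its value was seen. The list was called upward by camera (adjusted p = 1.24e-10, and 0.0446 with an estimated correlation). Both lists match themes known for the model and are not independent evidence of direction. In control replicate 1 the matrix list mean was 6.98, against 7.29 ± 0.03 (SD, n = 4) in the other controls.

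Genes of the VEGF response and of endothelial tip cells, the leading cells of vascular sprouts, formed another rising group, with 7 of 18 measured members higher and 11 not past the threshold. With p adjusted over the list alone, 9 were higher. The 7 included Esm1, Pdgfb, Apln and the potassium channel subunit Kcne3 (1.96 ± 0.24). Of the members of this list 8 are also in other lists, among them Esm1, Pdgfb, Apln and Nid2, so its call is not separate from theirs. By camera the list was called upward (adjusted p = 3.46e-10, and 0.0079 with an estimated correlation). In the Notch pathway 2 of 16 genes passed, both higher: the ligand Jag2 (2.27 ± 0.25, adjusted p = 0.000744) and the target gene Hey1 (1.75 ± 0.34, adjusted p = 0.0208). Adjusted over the list alone, 6 were higher and 1 lower, and camera called the list upward (adjusted p = 0.00053, and 0.0494 with an estimated correlation). The call of Hey1 ended without knockout replicate 3 or 4 or control replicate 3, 4 or 5 (adjusted p up to 0.0635), while 4 members passed without knockout replicate 5.

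Myc, a transcription factor of growth and proliferation, was 3.25-fold higher (log2 fold change 1.70 ± 0.18, adjusted p = 0.000732), at 6.99 ± 0.35 against 5.29 ± 0.27 (SD, n = 5). Of 25 genes in the list of MYC and its targets, 2 passed, Myc itself and Pa2g4 (0.57 ± 0.11), and 4 were higher adjusted over the list alone. The camera test gave an upward call for the list (adjusted p = 3.63e-06, and 0.0156 with an estimated correlation), with a median log2 fold change of 0.26. It matches a theme known for the model and is not independent evidence of direction. Of 20 cell cycle genes, Ccna2, a cyclin, passed (1.07 ± 0.22), and 13 were higher adjusted over the list alone. Camera called that list upward (adjusted p = 5.76e-11), but not with an estimated correlation (adjusted p = 0.054). The call of Pa2g4 ended without control replicate 4 or 5 (adjusted p up to 0.0554), and that of Ccna2 without knockout replicate 1, 2, 3 or 5 or control replicate 3, 4 or 5 (up to 0.0855). In the cell cycle list 3 passed without control replicate 1 and 2 without control replicate 2.

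Smaller changes were seen in receptors and regulators. Of 15 scavenger and endocytic receptors, Scarb2 (-0.61 ± 0.10) and the mannose receptor Mrc1 (-0.57 ± 0.13) fell. With p adjusted over the list alone, 1 was higher and 5 were lower. Camera called that list downward (adjusted p = 0.00723), but not with an estimated correlation (adjusted p = 0.208). Of its members 6 are also in other lists, among them Mrc1, Stab1 and Stab2 in the sinusoidal list. Its call is therefore not separate from that of the sinusoidal list. Of 25 endothelial transcription factors, Maf, Meis2 (-0.59 ± 0.09) and Meis1 (-0.57 ± 0.13) fell and 22 did not pass. Adjusted over the list alone, 2 were higher and 3 lower, and camera did not call the list (adjusted p = 0.664), while fry called it in either direction (adjusted p = 1.03e-08). The call of Mrc1 ended without knockout replicate 1, 2 or 4 or control replicate 2, 3, 4 or 5 (adjusted p up to 0.107), and that of Meis1 without any array except knockout replicate 4 and control replicate 1 (up to 0.115).

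Single members passed in 3 more lists. Id1, a target of BMP signalling, rose by 0.86 ± 0.15 on the log2 scale and was the 1 member past the threshold of 15 BMP and TGF-beta response genes, also adjusted over the list alone. Camera's upward call of that list (adjusted p = 0.0433) ended with an estimated correlation (adjusted p = 0.364) and without knockout replicate 2, 3 or 4 or control replicate 1 (adjusted p up to 0.185). Ptgis, the prostacyclin synthase, rose (1.18 ± 0.22) among 15 vasoregulatory and shear response genes. With p adjusted over the list alone, 7 were higher and 1 lower, and camera called the list upward (adjusted p = 0.000253), but not with an estimated correlation (adjusted p = 0.267). Control replicate 1 stood apart in both lists: its vasoregulatory mean was 6.00, against 6.86 ± 0.11 (SD, n = 4) in the other controls and 7.19 ± 0.15 (SD, n = 5) in the knockout, and its BMP and TGF-beta mean 7.12, against 7.61 ± 0.04 and 7.69 ± 0.14, so part of each rise came from this array. Sele, E-selectin, rose (1.03 ± 0.22) among 16 leukocyte adhesion and chemokine genes, of which 6 were higher adjusted over the list alone. Camera called them upward (adjusted p = 0.000736, and 0.0334 with an estimated correlation). The call of Ptgis ended without knockout replicate 2 or control replicate 3 or 4 (adjusted p up to 0.0555), while 2 members of its list passed without knockout replicate 1 or 5 or control replicate 1. The call of Sele ended without any array except knockout replicate 2 and control replicate 1 (adjusted p up to 0.103).

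None of 16 interferon response genes passed in limma, 0 also adjusted over the list alone, and 3 had an unadjusted p under 0.05. Camera did not call the list (adjusted p = 0.478), nor did fry directionally (0.395), but fry called it in either direction (0.0447). Gbp3 was at 0.36 ± 0.12 and Ifit2 at -0.41 ± 0.14. None of 8 MHC class II genes passed in limma, with 3 higher adjusted over the list alone and 4 with an unadjusted p under 0.05. Fry called them directionally (adjusted p = 0.00995). H2-Eb1 was at 0.51 ± 0.16 and H2-Aa at 1.16 ± 0.37. Camera called this list upward (adjusted p = 0.00043), but not with an estimated correlation (adjusted p = 0.054).

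**Figure D3:**
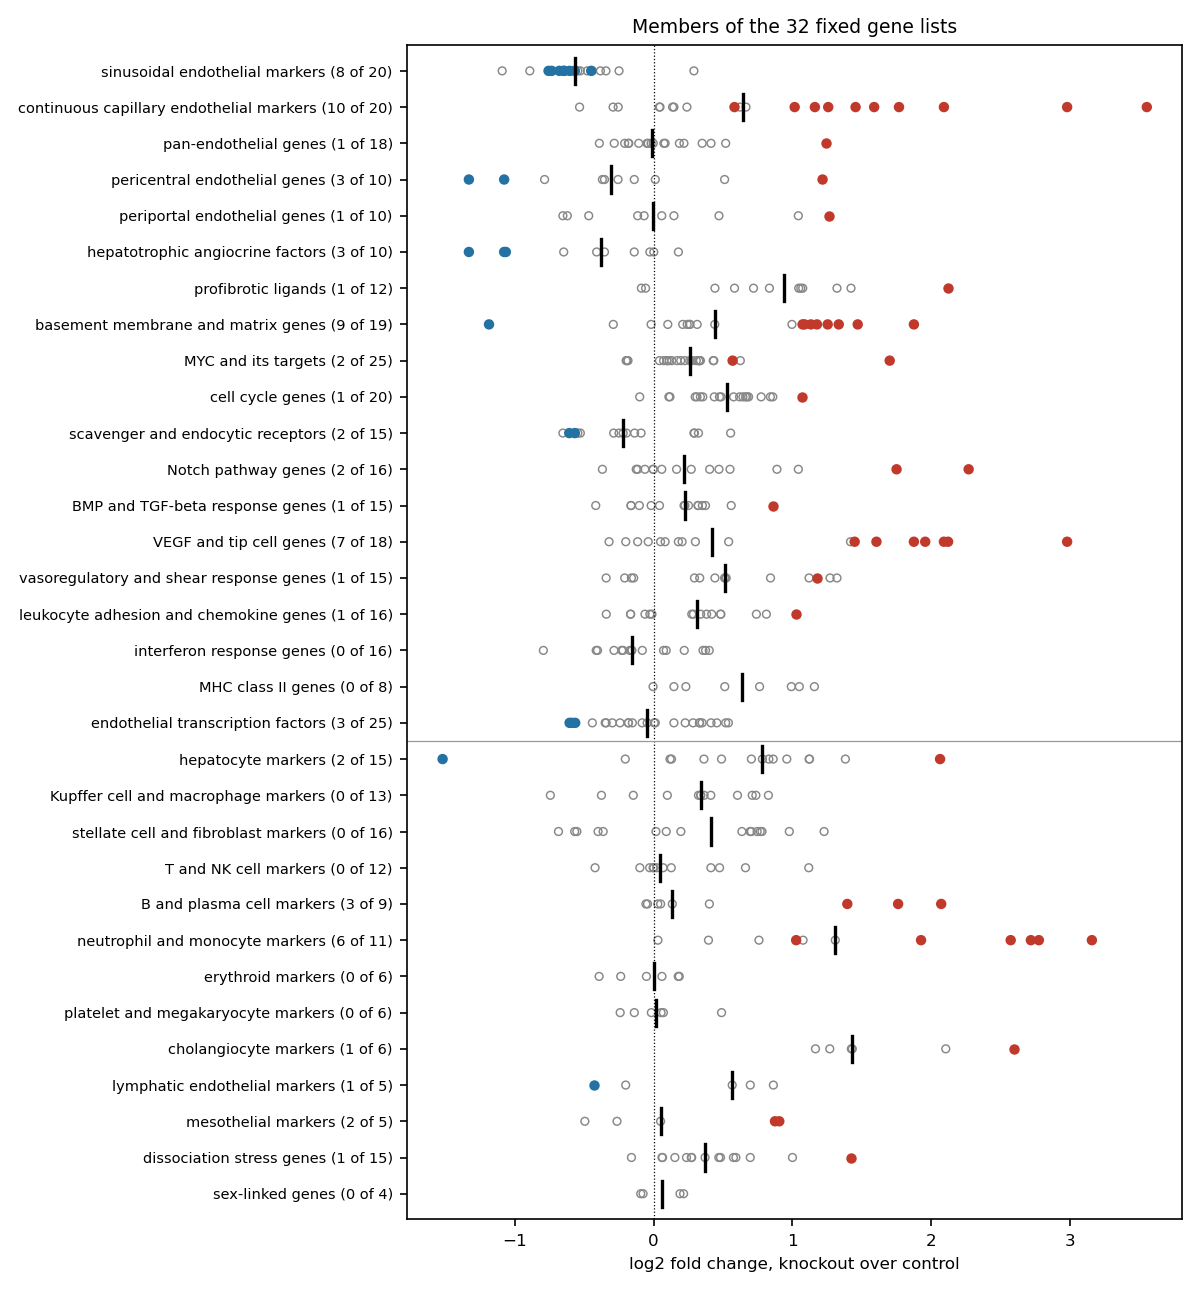
Log2 fold change of knockout over control (x axis) for each measured member of the 32 lists, with endothelial programmes above the grey line and other cells and technical lists below it. Filled points passed the threshold (red higher, blue lower), open points did not, black bars mark list medians, and the numbers give members past the threshold of those measured, such as 8 of 20 sinusoidal endothelial markers.

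Markers of other cells moved with the group labels too. Neutrophil and monocyte markers rose, with 6 of 11 past the threshold, 9 of 11 higher adjusted over the list alone and no group overlap in the list mean, which was 4.91 ± 0.58 in the knockout and 3.30 ± 0.23 in the control (SD, n = 5). S100a8 (log2 fold change 3.16 ± 0.53), S100a9 (2.78 ± 0.43), Ngp (2.72 ± 0.42) and Retnlg (2.57 ± 0.53) rose. Their control means of 3.73, 3.83, 3.03 and 2.72 lay near or under the array median of 3.71. An upward call came from camera (adjusted p = 1.28e-11, and 0.0355 with an estimated correlation). Among B and plasma cell markers the immunoglobulin heavy chain Ighm (2.07 ± 0.19), the joining chain Jchain (1.40 ± 0.23) and Ebf1 (1.76 ± 0.22) rose, 3 of 9 also adjusted over the list alone. The list was called upward by camera (adjusted p = 0.000157), but not with an estimated correlation (adjusted p = 0.054). The call of Retnlg ended without knockout replicate 4 or control replicate 2, 3, 4 or 5 (adjusted p up to 0.0739).

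Bile duct and hepatocyte markers varied between the knockout pools. The cholangiocyte list mean lay at 6.05, 6.56 and 5.23 in knockout replicates 1, 2 and 4 and at 4.65 and 4.26 in replicates 3 and 5, against 3.68 ± 0.42 (SD, n = 5) in the controls. Of its 6 measured genes Tspan8 passed (2.60 ± 0.58), and 6 were higher adjusted over the list alone. By camera the list was called upward (adjusted p = 1.98e-07), but not with an estimated correlation (adjusted p = 0.0842). The hepatocyte list mean was 8.21 and 7.99 in knockout replicates 1 and 4, between 6.46 and 6.83 in the other knockout pools, and 6.61 ± 0.20 in the controls. In that list Tat rose (2.06 ± 0.40) and Cyp2e1 fell (a call that ended without knockout replicate 1 or 2 or control replicate 3, 4 or 5, adjusted p up to 0.0781), 13 of 15 did not pass, and 2 were higher and 1 lower adjusted over the list alone. Camera called it upward (adjusted p = 0.00036), but not with an estimated correlation (adjusted p = 0.364). The call of Tspan8 ended without any array except knockout replicate 5 (adjusted p up to 0.117), without which 4 members passed. That of Tat ended without knockout replicate 1 or control replicate 3, 4 or 5 (adjusted p up to 0.0596).

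The main count changed with these list means as covariates. With the hepatocyte list mean 244 genes passed, with the cholangiocyte mean 62 and with the neutrophil mean 0 by limma. With the neutrophil mean 1086 of the 24704 genes had an unadjusted p under 0.05 by limma, fewer than chance alone gives. Of the 529 genes, chosen on these same arrays, 263 kept an unadjusted p under 0.05 in the same direction. The neutrophil mean shared 80.7% of its variance with the groups, and the cholangiocyte mean shared 61.4%. The overlap of the neutrophil mean by itself makes standard errors 2.27 times as large where the residual spread stays the same. Of 66 named genes past the threshold, 46 kept their call with the hepatocyte mean, 16 with the cholangiocyte mean and 0 with the neutrophil mean. The lost calls do not by themselves make other cells the source. Most fold changes stayed, but that does not argue against other cells either. The neutrophil and cholangiocyte means overlap with the groups, and the 529 genes were chosen on the same arrays. Of the 529 genes, 529 kept their sign with the hepatocyte and cholangiocyte means and 521 with the neutrophil mean, and the log2 fold changes were at a median of 0.987, 0.907 and 0.910 of their main values (quartiles with the neutrophil mean 0.652 and 1.14). Over all 24 alternatives Aplnr stayed between 3.42 and 4.22, Cd34 between 1.47 and 1.88 and Cd84 between -1.73 and -1.42. In contrast, Lcn2 went down to 1.27, Dsg2 to 1.14, Tm4sf4 to 0.91 and Tspan8, part of the cholangiocyte mean, to 0.18. Some called members of endothelial lists shrank as well: Cd55 to -0.07, Lpl to 0.28, Clu to 0.24 and Ptgis to 0.40. The last 2 covariates were chosen after seeing the data.

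Markers of Kupffer cells and of stellate cells, the liver's macrophages and pericytes, did not pass the test. None of 13 Kupffer cell and macrophage markers and none of 16 stellate cell and fibroblast markers passed in limma, 0 and 0 also adjusted over each list alone, and 0 and 5 had an unadjusted p under 0.05. Camera called neither (adjusted p = 0.161 and 0.150), nor did fry directionally (both 0.699). Camera called both upward without control replicate 4 (0.00352 and 0.0336) or 5 (0.0409 and 0.0450), and stellate cells also without knockout replicate 4 (0.0141). With the hepatocyte list mean as a covariate both were called upward (0.0403 and 0.00586), and with the neutrophil mean the stellate list was called downward (0.0415). Cd68 was at 0.83 ± 0.44, Cd163 at -0.74 ± 0.42, Col1a1 at 1.23 ± 0.33 and Ngfr at -0.57 ± 0.19. Both list means were lowest in control replicate 1, at 5.37 against 7.38 ± 0.59 for Kupffer cells and at 5.65 against 7.09 ± 0.33 for stellate cells in the other controls (SD, n = 4).

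The remaining lists showed few changes. Mesothelial markers Wt1 (0.91 ± 0.17) and Gpm6a (0.87 ± 0.20) rose, 2 of 5 also adjusted over the list alone, and the lymphatic endothelial marker Itga9 fell (-0.43 ± 0.09), 1 of 5, with 3 higher and 1 lower adjusted over the list alone. Camera called neither list with all arrays and no covariate (adjusted p = 0.116 and 0.263). It called the mesothelial one upward without control replicate 1 (0.0281) and with the hepatocyte (0.0157) or cholangiocyte (0.00254) list mean as a covariate, and fry called both lists in either direction (0.0497 and 0.0228). No T and NK cell, erythroid, platelet or sex-linked gene passed in limma, 0 in each also adjusted over the list alone, and 2, 0, 1 and 0 had an unadjusted p under 0.05. Camera called none of these lists (adjusted p = 0.116, 0.764, 0.764 and 0.764), except T and NK cells upward without control replicate 2 (0.0257), nor did fry directionally (0.255, 0.791, 0.791 and 0.865). The erythroid median was 0.00, with a mean of -0.04 and a test downward. Ccl5 was at 1.12 ± 0.34, Nkg7 at 0.48 ± 0.18, Klf1 at -0.24 ± 0.11, Epor at -0.39 ± 0.23, Pf4 at 0.49 ± 0.21, Gp9 at -0.24 ± 0.20, Uty at 0.22 ± 0.17 and Xist at -0.08 ± 0.10. Of 15 dissociation stress genes Nr4a1 rose (1.42 ± 0.26), with 2 higher adjusted over the list alone. Camera called that list upward (adjusted p = 0.000353), but not with an estimated correlation (adjusted p = 0.300). The calls of Itga9 and Gpm6a ended without 7 and 8 of the 10 arrays in turn (adjusted p up to 0.0826 and 0.119), among which knockout replicates 1, 2 and 4 and control replicates 3, 4 and 5 ended both. Control replicate 2 ended that of Itga9, and knockout replicates 3 and 5 that of Gpm6a, while 2 lymphatic markers passed without knockout replicate 5. The call of Wt1 ended without control replicate 4 or 5 (up to 0.0578).

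**Figure D4:**
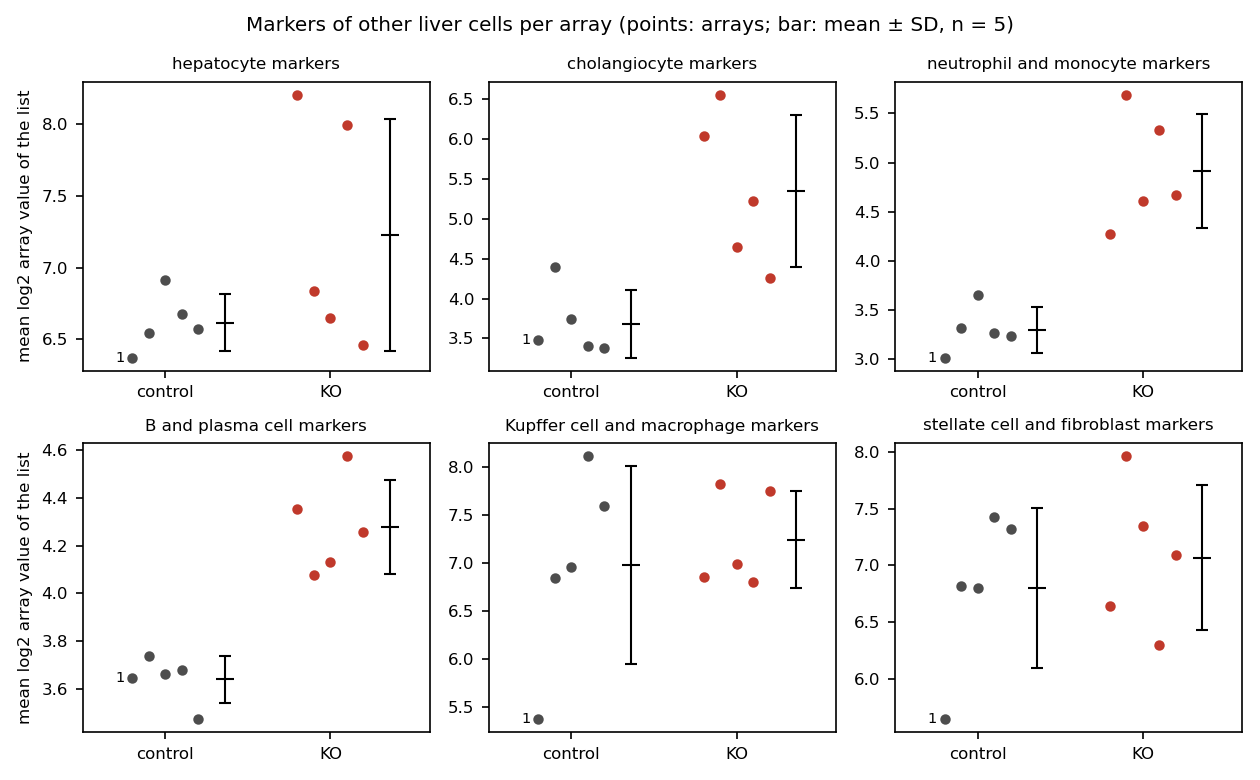
Mean log2 array value (y axis) of 6 marker lists in the control and knockout (KO) groups, 1 point per array with replicates 1 to 5 from left to right, bars for the mean ± SD (n = 5), and control replicate 1 marked. Neutrophil and monocyte markers did not overlap between the groups (4.91 ± 0.58 against 3.30 ± 0.23), and control replicate 1 was lowest for Kupffer cell (5.37) and stellate cell (5.65) markers.

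Across the lists, camera called 20 of 32, 16 upward and 4 downward. With an estimated correlation 9 of the 20 kept their call. These were the sinusoidal, capillary, profibrotic, matrix, MYC, Notch, VEGF, leukocyte adhesion and neutrophil lists. With the hepatocyte mean as a covariate camera lost the pericentral endothelial call (adjusted p = 0.112). With the neutrophil and cholangiocyte means it lost those of the pericentral (0.168 and 0.573), scavenger (0.264 and 0.327), BMP and TGF-beta (0.440 and 0.146), leukocyte adhesion (0.421 and 0.314) and dissociation stress (0.284 and 0.109) lists. The neutrophil mean also ended the vasoregulatory (0.180) and cholangiocyte (0.183) calls, and the cholangiocyte mean the hepatocyte call (0.893). With the dimmer 0.5 of the genes left out the pericentral call ended (0.0560), and the BMP and TGF-beta call ended under both filters on dim genes (0.0609 and 0.106), with array weights (0.122) and with the Kupffer (0.0718) and stellate (0.0941) means. Of the different list genes measured 64 passed, and 42 passed without control replicate 4 or without control replicate 5. By fry 16 lists were called directionally and 25 in either direction. The camera calls that fry did not give directionally were those of the BMP and TGF-beta (0.228), vasoregulatory (0.103), hepatocyte (0.260) and dissociation stress (0.228) lists, and in either direction that of the last (0.0894).

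The genes beside Clec4g, the driver gene of the Cre line, changed as a local cluster. Of the 5 measured genes on each side, 4 passed upward: Fcor (10.5-fold), Mcemp1 (8.57-fold), Cd209a (4.78-fold) and Trappc5 (4.04-fold, log2 fold change 2.01 ± 0.12, adjusted p = 6.37e-05). Fcer2a, the gene next to Clec4g on the same side as Trappc5, was at 1.51 ± 0.39 with an adjusted p of 0.0813 (0.00716 without control replicate 1). Clec4g itself fell, a call that ended without knockout replicate 1 or 2 or control replicate 2, 3 or 4 (adjusted p up to 0.0598). Cd209b was at -1.09 ± 0.25 with an adjusted p of 0.0529, and it passed without knockout replicate 5 or control replicate 1 (adjusted p down to 0.00184). Fcor and Mcemp1 met the rule for named genes, and the others were chosen after their values were seen.

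**Figure D5:**
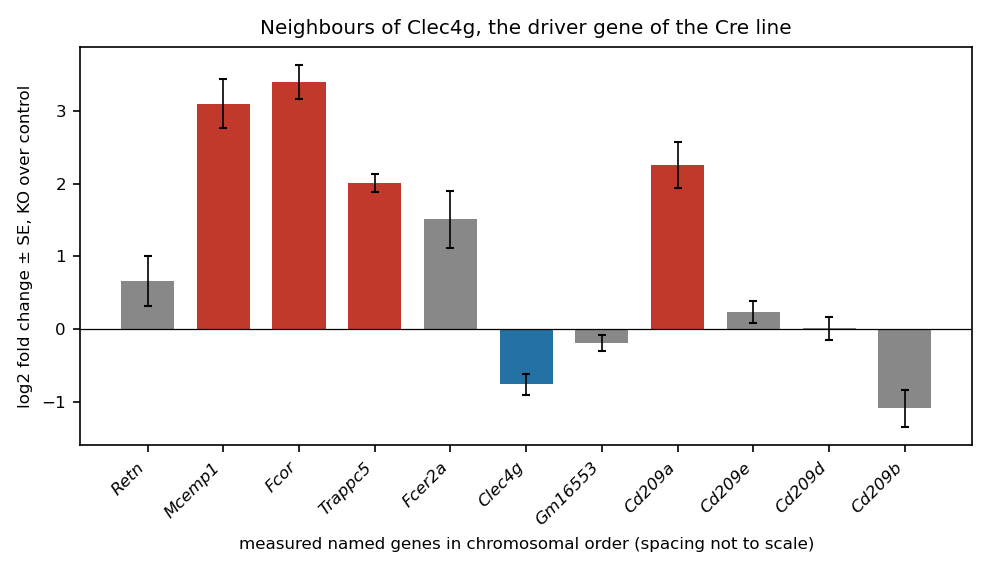
Log2 fold change ± SE of knockout over control (y axis, 5 arrays per group) for Clec4g and the 5 measured named genes on each side, in chromosomal order with spacing not to scale. Red bars passed the threshold upward, the blue bar downward and grey bars did not pass; the tallest bar is Fcor at 3.40 ± 0.23.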

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

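The tests of control replicate 1, of the Gata4 probe set and of other windows along the genome were chosen only after the results were seen, and so were the neutrophil covariate and the omission of the genes next to Clec4g.

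A value was taken as standing apart when its gap to the nearest other value of its group was large against the group's range. Of 242 groups of 5 values, 15 held such a value, where chance gives about 1 in 20, or 12.1. The differences below are from the mean of the other 4 arrays of the group, on the log2 scale. In the knockout, Emcn (0.31) and Wnt2 (-0.76) stood apart in replicate 1, Lpl (1.04) in replicate 2 and Fabp4 (-0.35) in replicate 3. Ngp stood apart in control replicate 5 (-1.14). The other 10 were in control replicate 1: Olfm1 (-0.52), Emcn (0.39), Fabp4 (0.90), Fn1 (-0.87), Kcne3 (0.73), Col1a1 (-0.69), Gp9 (0.89), and the means of the matrix (-0.31), BMP and TGF-beta (-0.50) and vasoregulatory (-0.86) lists.

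Control replicate 1 stood apart from the other 9 arrays. An array of the other group under this label is argued against, since over the genes called without it its median place on the way from the other controls to the knockout was 0.147 (quartiles -0.30 and 0.59). Fewer macrophages and stellate cells as the whole cause is left open. Of the 2703 genes that lay 1 or more from the other controls 54.1% lay above them, which under the limit set for the test counted against it. That was set aside after the outcome was known, since arrays brought to one distribution balance rises against falls whatever the cause. Noise on the array may contribute: 5.89% of probe sets for olfactory, vomeronasal, trace amine and taste receptors lay above its median, against 2.20% to 4.19% in the other 9 arrays, which is outside their range but by less than the limit set for the test. Apart from that difference in cells no biological explanation was tested, as the labels give none for a single control.

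The Gata4 probe set was not lower in the arrays labelled knockout. Gata4 RNA from stellate cells, which express this gene, as its main source is argued against, since within groups its value had a slope of 0.0271 on the stellate list mean (95% interval -0.234 to 0.288). Probes outside the deleted part of the gene, or uncut Gata4 in part of the cells, could each leave the value where it is. Neither was tested, since the probe locations are not given in the sources used here.

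Genes next to Clec4g were higher in the arrays labelled knockout, 4 of the 10 neighbours past the threshold. Neutrophils and monocytes as the source for these genes as a set are argued against only as far as their list mean tracks these cells. With that mean as a covariate the median log2 fold change of the 4 genes was 2.28, between 1.19 and 3.00. Other immune cells were not tested as a source. No call was left under that covariate for any gene. Its overlap with the groups by itself makes standard errors 2.27 times as large where the residual spread stays the same. Mcemp1 lost most of its change and went from 3.10 to 1.19 ± 0.48, Fcor from 3.40 to 3.00 ± 0.54, Trappc5 from 2.01 to 1.75 ± 0.28 and Cd209a from 2.26 to 2.81 ± 0.74. Extra copies of the Clec4g region carried by the Cre transgene may be the source and cannot be told apart from a response to the deletion, since the transgene and the deletion go together in the knockout mice. The labels call the sibling controls WT, and give no separate genotype for the transgene. That test predicted more such genes here than around any other gene, which was not found: 11 of 24460 other windows held 4 or more, up to 6. The limit was loosened after this outcome was known, because the explanation forbids nothing elsewhere and in all 11 windows the genes past the threshold were immunoglobulin genes only.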

How the results depend on the processing

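The neutrophil and cholangiocyte covariates and the omission of the genes next to Clec4g were chosen after seeing the data. Over all 24 alternatives the Gata4 log2 fold change stayed between -0.20 and 0.16 (adjusted p 0.495 or higher). Without 1 array at a time it ranged from -0.20 to -0.06, the genes past the threshold from 287 to 737 (higher 182 to 394, lower 105 to 343), those at least 2-fold changed from 172 to 311, the list genes past it from 42 to 75 and the lists called from 19 to 22. The low of 42 came without control replicate 4 and without control replicate 5. All 529 genes kept their sign in these 10 runs, which was certain in advance for the 503 whose groups did not overlap. Of the 529 genes, 285 to 490 kept their call. Quantile normalization and median centring gave 529 genes, which could hardly differ, since the arrays already shared 1 distribution. The filters on dim genes gave 553 and 592, and an intensity trend with robust variances 527. The Kupffer and stellate covariates gave 581 and 514, and the omission of the genes next to Clec4g 525. The mean of probe sets also gave 529, but only 1 gene had more than 1. Array weights gave 1070 (616 higher, 454 lower), the hepatocyte covariate 244 (159 and 85), the cholangiocyte covariate 62 (52 and 10, all 62 at least 2-fold, 15 list genes) and the neutrophil covariate 0 (0 and 0, 0 at least 2-fold, 0 list genes). These covariates widen the standard errors by their overlap with the groups (1.16, 1.61 and 2.27 times); any other cause was not tested. With an estimated correlation 9 lists were called. The replicate number as a block gave 275 genes (200 and 75), of which 256 were among the 529, and ended 21 of 66 named calls and 0 list calls. No sign was found that the numbers pair the arrays: 0 of 5 pairs correlated above 0.1 after the group means were removed. Likewise, 0 arrays correlated best with the array of the same number. With 5 pairs, 1 of them holding control replicate 1, a shared day or litter cannot be excluded. With the neutrophil covariate S100a8 (-0.29), S100a9 (-0.0445) and Retnlg (-0.66), which are part of it, turned negative, and the BMP and TGF-beta (adjusted p 0.440) and stellate (0.0415) lists turned downward. With the cholangiocyte covariate the dissociation stress list did (0.109). The cause was not tested. Of 66 named calls, 45 held under every alternative except the covariates and the block, and 0 under every one, as the neutrophil covariate left none, though under it 521 of the 529 genes kept their sign, at a median of 0.910 of their log2 fold change. Of the named genes not past the threshold, 4 passed under some alternative. The signal over background could not be judged without detection calls, so a small change in a dim gene can be missed.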

Other observations

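The tests of hepatocyte zonation, lysosomal genes and hypoxia response genes used lists drawn up after the main results had been seen, with their limits written before the tests were run, and the genes named below without a list were chosen after their values were seen.

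Some single genes higher in the knockout are given as values, without a test of any group they belong to. The transcription factors Meox2 (log2 fold change 1.70 ± 0.28) and Tcf15 (1.35 ± 0.20), known from fatty acid uptake in capillaries of heart and muscle, Pparg (1.56 ± 0.20) and Rbp7 (2.19 ± 0.16, adjusted p = 6.37e-05) rose. The fatty acid synthase Fasn (1.26 ± 0.11) rose too. The efflux pump Abcb1a (1.96 ± 0.22) and the glucose transporter Slc2a1 (1.87 ± 0.40) were higher. The call of Slc2a1 ended without knockout replicate 1, 2, 4 or 5 or control replicate 3 or 5 (adjusted p up to 0.0941).

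Further single genes that passed, also without a test of a group, were the keratins Krt18 (2.25 ± 0.45) and Krt8 (1.44 ± 0.33), desmoplakin, Dsp (2.00 ± 0.38), Pkhd1 (1.96 ± 0.44) and Cd24a (1.71 ± 0.38). Epcam was at 2.11 ± 0.55 (adjusted p = 0.0811) and Krt19 at 1.17 ± 0.30 (adjusted p = 0.0774), and both passed without knockout replicate 5 (0.0337 and 0.0386). These calls depended on single arrays: those of Krt18 and Dsp, like those of Krt8 and Cd24a, ended without knockout replicate 1, 2 or 4 or control replicate 3, 4 or 5 (adjusted p up to 0.0712 and 0.0637, and 0.121 and 0.113), and those of Krt8 and Cd24a also without control replicate 2. The call of Pkhd1 ended without any array except knockout replicate 5 (up to 0.117). The immunoglobulin light chain constant gene Igkc rose (2.40 ± 0.26), while the B cell markers Cd79a (0.40 ± 0.20) and Ms4a1 (0.03 ± 0.13) did not pass. Il13ra2, a decoy receptor for interleukin 13, had the lowest log2 fold change of all genes past the threshold (-2.61 ± 0.48, adjusted p = 0.0177), with group values that overlapped and a call that ended without knockout replicate 2 or 4 or control replicate 3, 4 or 5 (up to 0.0542). Mertk, a receptor for the uptake of dead cells, fell (-0.80 ± 0.13).

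The count of 529 genes was set against other splits of the 10 arrays into 5 and 5. Of 100 splits drawn from 126, the real one included, 1 gave as many genes, and the highest other gave 0. That is the lowest share that 100 splits can show, so a chance division of the arrays is unlikely but not excluded. The other splits mix the labels, so a real difference adds to their spread and lowers their counts. Any difference that goes with the labels, such as the cells in the isolates, could give the same result.

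A hypothesis from single hepatocyte genes such as Cyp2c29 is that the hepatocyte RNA in the isolates shifted its zonation. Of 13 pericentral genes 11 were lower, and of 13 periportal genes 11 were higher, 0 of either past the threshold in limma and 7 of each with an unadjusted p under 0.05, of which Aldh1a1 (0.50) and Ass1 went against the hypothesis. The mean of the pericentral minus that of the periportal list was -0.64 in the knockout and 0.28 in the control arrays, with an exact two-sided permutation p of 0.0159, not adjusted for the 3 hypotheses tested, which is consistent with the hypothesis. Camera on each list gave less: with an estimated correlation p was 0.0397 for the pericentral and 0.134 for the periportal list, against 0.000336 and 7.25e-05 at the preset one. It was lowest in knockout replicates 1 and 4 (-1.09 and -1.32), the pools with the highest hepatocyte list means, and at 0.08 in knockout replicate 3 it lay among the controls. More or less hepatocyte RNA alone is argued against only as far as both lists follow its amount. The 2 lists had medians of -0.25 and 0.68, a difference of -0.92. The periportal mean was 5.35 and 5.96 in knockout replicates 1 and 4, 4.43 to 4.76 in the other knockout pools and 4.33 to 4.52 in the controls. The pericentral mean was 4.27 and 4.64 in replicates 1 and 4, against 4.48 to 4.92 in the controls. Whether the pericentral list follows the amount was not tested. Ass1, a periportal gene, was lower (-1.50 ± 0.55, adjusted p = 0.239).

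A second hypothesis, from Ctsl and Scarb2, is a lower level of lysosomal genes as a class. Of 32 such genes 24 were lower (median -0.17), 0 past the threshold in limma and 9 with an unadjusted p under 0.05, of which Cd63 was higher (0.99). The predicted result was not found: camera gave p = 0.377 with an estimated correlation, against 0.00293 at the preset one. A further hypothesis, from Vegfa, Slc2a1 and Cxcr4, is a hypoxia response. Of 17 genes 13 were higher (median 0.09), 0 past the threshold in limma and 2 with an unadjusted p under 0.05, Ankrd37 higher (0.81) and P4ha2 lower (-0.44), and the predicted result was again not found (p = 0.0911 with an estimated correlation). Under the limits written beforehand both outcomes counted against the hypotheses. Those limits were set aside after the outcomes were known: a p above the threshold sets no bound on the change, the lysosomal genes varied together (estimated correlation 0.396), and most members of both lists lay on the predicted side, so both hypotheses are left open without support.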
